A study of Rattus norvegicus with 2 samples.

How the data were processed

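Small RNA from the hippocampus of Sprague-Dawley rats was sequenced on a HiSeq 2000 instrument, and 2 libraries were analysed, 1 from the temporal lobe epilepsy (TLE) group and 1 from the control group. Total RNA was isolated with the mirVana kit, per the labels' protocols. The same protocol text goes on to describe biotinylated cRNA, a step of microarray work, and the adapters, read length and small RNA library kit are not given in the sources used here. Whether a library pools several rats is not given either.

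Each deposited file holds whole-number read counts for the same 419 miRNA names, of which 356 are named rat miRNAs and 63 are numbered predictions (novel_mir). The authors deposited these counts without normalization. The trimming, aligner, genome build, miRNA database release and counting rules are not given in the sources used here, so no coordinates are printed and reads shared by near-identical family members (let-7, miR-181, miR-30) could have been split in ways that cannot be followed. In every listed name the larger of the 2 counts was at least 9. The libraries do not use the same names throughout: miR-219 has counts under its older names (miR-219-5p, miR-219-1-3p, miR-219-2-3p) in the control library and under its newer names (miR-219a-5p, miR-219a-1-3p, miR-219a-2-3p) in the TLE library. These 3 pairs were added together, which left 416 names. A rule for older names, fixed before the data were examined, equates miR-219 with miR-219a for matching list members, but it did not itself provide for adding counts.

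Both files also carry a deposited column of p-values under a header that calls them detection p-values. In the TLE file all 392 p-values above 0 equalled, within 5%, the 2-sided Audic-Claverie p of that row's 2 counts, a test of 2 single libraries based on Poisson counts, and the other 27 were listed at 0 where the recomputed value was under 1e-300. The column fits a ratio of library totals, TLE over control, of 1.022. In the control file 4 of 408 p-values above 0 matched their own row in this way. A test on the reads of 2 libraries compares those libraries and not the conditions, so these columns were used only to find out what they hold and for 1 alternative scaling.

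The depth was 5086420 counts in the TLE library and 6703030 in the control library. Counts were scaled by the TMM method of edgeR 4.0.16 in R 4.3.3 (factors 1.067 for TLE and 0.937 for control). The log2 ratio of TLE over control was taken after 0.5 was added to each raw count. Each ratio carries an exact Clopper-Pearson 95% interval, which covers counting error only: reads without molecular identifiers are not independent molecules, and no interval here includes variation between animals. A count of 0 allows up to 3 counts, or 0.553 CPM in the TLE library and 0.478 in the control library. Folds set against these 3 counts take the count of the other library as exact. Names with a mean of at least 10 CPM over the 2 libraries entered the summaries, and a 2-fold ratio was used as a size threshold.

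With 1 library per group there is no replicate check, no test between the groups and no p-value for any difference. Names for the text were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest log2 ratios above the floor whose counting interval excludes 0, the 5 most abundant names of each library, and members of 16 fixed lists (the most abundant and the most different). After the data were seen, the same rule was repeated on names with a count in both libraries. Each list is described by the median log2 ratio of its members above the floor, with a 95% interval from 2000 Poisson draws of the counts and its percentile among 10000 random lists of the same size matched on mean expression. For some closing tests, hairpins were matched by name to the RefSeq table of the rat assembly GRCr8, which placed 325 of 353 known names; it was used only for which miRNA genes lie next to each other or within another gene.

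The alternatives fixed before the data were examined were total-count scaling, DESeq2 1.42.0 size factors, the total without the 10 most abundant names, no floor, a floor of 100 CPM, 5 counts added, a 1.5-fold threshold, thinning of the control library to the TLE total, and the summed counts of each list. Restricting to names counted in both libraries, scaling by the library totals that the p-value column implies, and keeping the miR-219 names apart were added after the data were seen. The scaling and ratio steps were tested on simulated counts for the 416 names in 1 TLE against 1 control library, with 200 names changed. Of the names above the floor, 100% of 55 changed 2.5-fold and 100% of 51 changed 4-fold passed the 2-fold threshold in the right direction, and 0% of 110 unchanged names did. These simulated counts held counting error only. Equally many names were raised and lowered by each fold, so the simulation did not test how the scaling handles an unbalanced change.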

Results

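The series profiled miRNAs in the hippocampus of rats in a chronic model of temporal lobe epilepsy. Rats of the TLE group had the lateral nucleus of the right amygdala stimulated for 20 min, and control rats were sham stimulated. RNA was taken 2 months later, and the labels give the rats' age as 3 months. The data comprise 1 TLE library with 5086420 miRNA counts and 1 control library with 6703030, so the values below compare these 2 libraries, and no difference could be set against a spread between animals. In both libraries the let-7 family made up most of the counts, with 79.5% in TLE and 82.5% in control. The 5 most abundant miRNAs were the same in both: let-7c-5p (32.9% of TLE counts and 32.3% of control counts), let-7f-5p (20.8% and 20.2%), let-7b-5p (10.3% and 12.6%), let-7a-5p (9.9% and 12.2%) and miR-128-3p (4.28% and 5.29%). The 10 most abundant names took 88.7% of the TLE counts and 91.6% of the control counts.

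The design implies a single comparison, the TLE hippocampus against the sham-stimulated hippocampus. Among miRNAs counted in both libraries, miR-341 was 7.46-fold higher in the TLE library, with 6293 counts against 975, and miR-345-3p was 6.82-fold higher, with 427 against 72. miR-124-3p, the classic neuron-enriched miRNA, was 3.28-fold higher and miR-598-3p 4.23-fold higher. The clearest differences the other way were in miR-448-3p, which lies within the serotonin receptor 2C gene (Htr2c) and was 6.03-fold lower in TLE with 475 counts against 3315, and in miR-204-5p, which is abundant in the choroid plexus and was 2.35-fold lower.

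Of the 416 names, 244 passed the floor of 10 CPM. Of these, 30 were at least 2-fold higher in the TLE library and 18 at least 2-fold lower. The ends of this ranking were taken up by names with no count at all in 1 library. Of the 30 higher names, 14 were listed at 0 in the control library, and of the 18 lower names 10 were listed at 0 in the TLE library, all 10 of them numbered predictions. Predictions at 0 in TLE ran from novel_mir_1 to novel_mir_60, and those at 0 in control from novel_mir_62 to novel_mir_93, without overlap. A 0 for a prediction can therefore mean that the number was not in use for that library, which was not tested. The 220 names counted in both libraries, a restriction made after the data were seen, gave 16 at least 2-fold higher and 8 at least 2-fold lower, while 196 (89.1%) differed by less than 2-fold. Which side held more names depended on the scaling: among these 220 names it was 24 higher against 3 lower by total counts, 13 against 19 without the 10 most abundant in the total, and 10 against 25 by the library totals behind the deposited p-values. Their median log2 ratio was -0.06, and the 5th and 95th percentiles were -0.90 and 1.19.

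**Figure D1:**
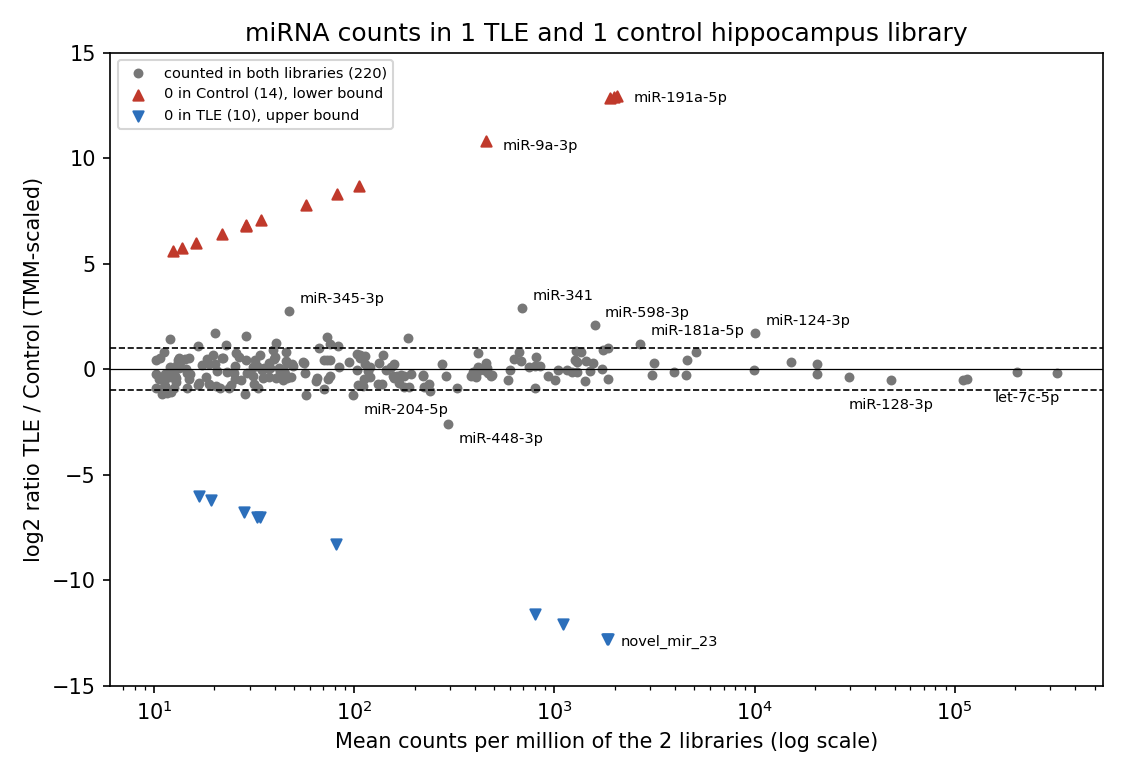
Log2 ratio of TLE over control (TMM-scaled) against mean CPM on a log axis, for the 244 names above the floor; each point is 1 miRNA, and dashed lines mark 2-fold. The 220 names counted in both libraries (grey circles) lie between the 6.03-fold lower miR-448-3p and the 7.46-fold higher miR-341, while the 14 names at 0 in control (red, lower bounds) and the 10 at 0 in TLE (blue, upper bounds), set against 3 counts, stand far apart from them.

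By the fixed rule, the 12 names with the highest ratio were all at 0 in the control library. They were miR-191a-5p (20875 TLE counts), miR-1839-5p (20281), miR-9a-5p (19182), miR-9a-3p (4640), miR-378a-3p (1075), miR-1298 (835), novel_mir_66 (583), miR-3099 (347), miR-409a-5p (294), miR-31a-5p (293), miR-409a-3p (223) and miR-3068-5p (165). miR-9 is a major miRNA of neural tissue. Against the 3 counts that a 0 allows, with the TLE count taken as exact, miR-191a-5p was listed 8047-fold higher in TLE and miR-9a-5p 7395-fold. The lower ends of their 95% counting intervals were somewhat lower, at log2 ratios of 12.68 and 12.55. The miR-219 arms were listed in the same way, with 9363 TLE counts of miR-219a-2-3p against 0 and 10795 control counts of miR-219-2-3p against 0, and once the older and newer names were added together the log2 ratio was 0.0045 (95% counting interval -0.036 to 0.045) for miR-219a-2-3p, -0.13 (-0.22 to -0.05) for miR-219a-5p and 0.50 (-0.36 to 1.39) for miR-219a-1-3p. No named miRNA other than the older miR-219 names was at 0 in the TLE library. The 10 lowest names were novel_mir_23 (24737 control counts), novel_mir_50 (24400), novel_mir_22 (14792), novel_mir_58 (10700), novel_mir_20 (1081), novel_mir_24 (451), novel_mir_8 (440), novel_mir_40 (377), novel_mir_37 (257) and novel_mir_30 (225), followed by miR-448-3p and miR-204-5p.

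Among names counted in both libraries, the 12 highest were miR-341, miR-345-3p, miR-598-3p, miR-455-3p, miR-124-3p, miR-134-5p, miR-92b-5p, miR-342-3p, miR-324-5p, miR-668, miR-181a-5p and miR-132-3p. The abundant ones were set within narrow counting limits: the log2 ratio was 2.90 (2.80 to 3.00) for miR-341, 2.08 (2.03 to 2.13) for miR-598-3p with 13366 TLE and 3656 control counts, and 1.71 (1.69 to 1.73) for miR-124-3p with 80860 and 28500. It was 1.5 (1.36 to 1.64) for miR-342-3p and 1.22 (1.18 to 1.25) for miR-181a-5p, with 19828 and 9845 counts. Thinner counts left wider limits, as in miR-324-5p with 93 against 39 counts and a log2 ratio of 1.45 (0.91 to 2.04), and in miR-455-3p with 162 against 56 and 1.73 (1.30 to 2.21). miR-345-3p stood at 2.77 (2.41 to 3.16), miR-92b-5p at 1.56 (1.33 to 1.79) and miR-668 at 1.27 (0.98 to 1.56).

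The 12 lowest were miR-448-3p, miR-204-5p, miR-298-5p, miR-483-5p, miR-551b-3p, miR-184, miR-146a-5p, miR-329-3p, miR-369-5p, miR-344b-1-3p, miR-99b-3p and miR-338-5p. The log2 ratio of miR-448-3p was -2.59 (95% counting interval -2.74 to -2.45), that of miR-204-5p -1.23 (-1.42 to -1.05) and that of miR-298-5p -1.21 (-1.46 to -0.97). miR-329-3p had 880 TLE and 2055 control counts and a log2 ratio of -1.01 (-1.13 to -0.90), while the other arm of its hairpin, miR-329-5p, which is not among these 12, was at 0.18. Several of the others were thinly counted: miR-483-5p had 37 against 98 counts, miR-184 40 against 103, and miR-344b-1-3p 39 against 85. Scaling by other methods moved every log2 ratio by between -0.24 and 0.19, which turned the direction of none of these 24 miRNAs, but moved let-7c-5p from -0.16 to 0.025 and let-7f-5p from -0.14 to 0.045 under total-count scaling.

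Members of the neuron-enriched list went both ways. Of the 9 counted in both libraries, 4 were higher in TLE and 5 lower, of which miR-129-5p, at -0.07, turns direction under total-count scaling. miR-124-3p (1.71), miR-153-3p (1.10), miR-138-5p (0.81) and miR-137-3p (0.70) had positive log2 ratios, while miR-128-3p, the most abundant of them, was at -0.49 with 217554 against 354286 counts and miR-129-1-3p at -0.70. The list's median was 0.70 with miR-9a-5p and miR-9a-3p, which were at 0 in control (percentile 98.9 of random lists), and -0.07 without them (percentile 28.3). Among miRNAs regulated by neuronal activity, miR-134-5p, a dendritic miRNA, was 2.95-fold higher (225 against 88 counts) and miR-132-3p, a target of the transcription factor CREB, was 2.27-fold higher (557 against 283). The other arm of the miR-132 hairpin, miR-132-5p, was at -0.49, miR-212-3p at -0.18, miR-212-5p at 0.37 and miR-485-5p at 0.36. The median of these 6 was 0.36, at percentile 82.6, and moved between 0.12 and 0.55 with the scaling. The other arm of the miR-485 hairpin, miR-485-3p, was not in the list and was at -0.83 with 883 against 1817 counts.

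All 4 members of the miR-181 family were higher in TLE under every scaling tried: miR-181a-5p by 1.22, miR-181b-5p by 0.92, miR-181d-5p by 0.79 and miR-181c-5p by 0.51 on the log2 scale. The median was 0.86, at percentile 94.1 of random lists, or 99.2 among names counted in both libraries. These members are close in sequence, and the ratio of their summed counts, 1.07 on the log2 scale, does not depend on how reads were divided among them. In the let-7 family, 7 of 8 members were lower and let-7d-5p was at 0.24. The median of -0.15 became 0.035 under total-count scaling. In the miR-30 family 4 of 5 members were higher, with a median of 0.17 that became -0.07 when scaled by the library totals behind the deposited p-values. In the list of miR-17/92 paralogous clusters, 2 of the 4 members above the floor were higher, among them miR-93-5p at 0.50, and miR-25-3p was at -0.25. The median of these 4 was 0.032, and negative (-0.21) by those totals. The members miR-17-5p, miR-19b-3p and miR-20a-5p lay under the floor.

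In the inflammation-associated list only 3 of the 6 listed miRNAs were in the table, and they went both ways. miR-146a-5p, a brake on innate immune signalling, was 2.12-fold lower in TLE, but with 43 against 106 counts. miR-21-5p was at -0.88 with 1277 against 2710 counts, and miR-146b-5p at 0.82 with 4533 against 2976. The median of -0.88 lay at percentile 2.17, whereas the summed counts gave 0.22 and the median without miR-146a-5p, at a floor of 100 CPM, was -0.029. Of the 2 measured microglia and leukocyte miRNAs, miR-142-5p was lower at -0.69 with 133 against 249 counts, and miR-150-5p was at -0.45 with 51 against 81 and a counting interval that includes 0 (-0.99 to 0.065).

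Markers of other cell types gave mixed values. Of the oligodendrocyte-enriched miRNAs, miR-219a-5p was at -0.13, miR-219a-2-3p at 0.0045, miR-338-3p at 0.46 and miR-338-5p at -0.89, with a median of -0.06 that became 0.12 under total-count scaling. Of the 6 astrocyte-associated miRNAs 4 were lower, miR-23a-3p at -0.70 among them, 2 were higher, miR-26a-5p at 0.32 among them, and miR-29a-3p, the most abundant, was at -0.22. Their median was -0.17, and 0.019 under total-count scaling. The erythroid miR-451-5p had 101 TLE and 100 control counts. Of the vascular miRNAs, miR-143-3p was at -0.20 and miR-145-5p at 0.17, with a median of -0.01 that moved between -0.26 and 0.17 with the scaling, while miR-126a-5p and miR-126a-3p had 83 and 39 TLE counts and were listed at 0 in control. The choroid plexus list was the lowest of the 16: miR-204-5p was at -1.23 and miR-204-3p at -0.74, with a median of -0.99 at percentile 8.62, or 0.83 among names counted in both libraries. In the miR-34 and miR-449 family, which ciliated cells express, miR-34c-5p was at -0.50 with 4560 against 7462 counts and miR-34b-5p at -0.44, with a median of -0.47. Of the miRNAs typical of other tissues, the muscle miRNAs miR-1-3p and miR-206-3p were at -0.84 and -0.39, liver miR-122-5p at -0.42 and endocrine miR-375-3p at 0.51, with a median of -0.40.

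The list of the imprinted Dlk1-Dio3 region, which holds the large brain-expressed cluster from miR-379 to miR-410 and other miRNAs between the same genes, had 29 members counted in both libraries and above the floor, of which 15 were higher in TLE and 14 lower, a division that moves with the scaling. Their median was 0.045, and the median of the 31 members including miR-409a-3p and miR-409a-5p was 0.10, at percentile 71.9, and between -0.15 and 0.28 under the other scalings. Members spread from 1.56 for miR-134-5p and 1.27 for miR-668 to -0.87 for miR-323-3p, with 3124 against 6603 counts, and -1.01 for miR-329-3p. The most abundant members, miR-434-3p, miR-485-5p and miR-127-3p, had log2 ratios of -0.06, 0.36 and 0.42.

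**Figure D2:**
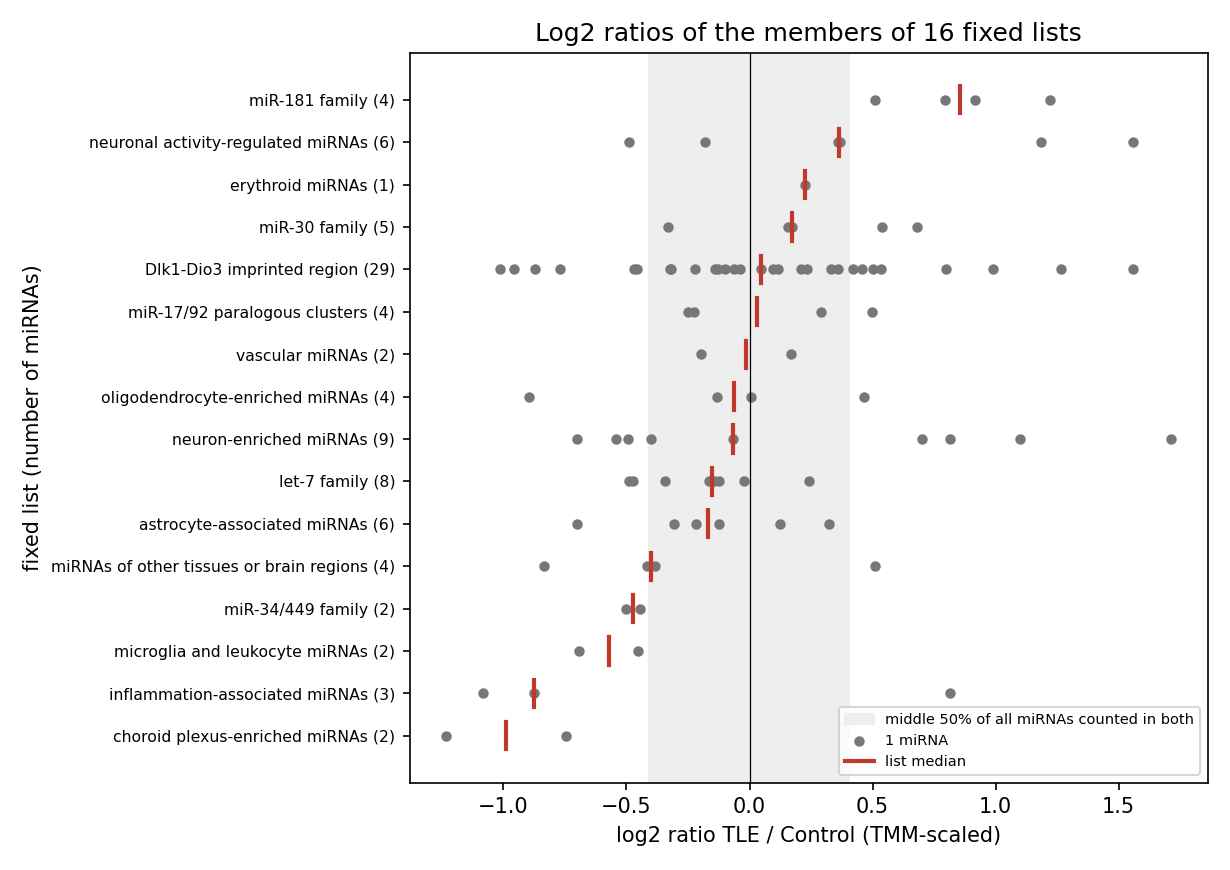
Log2 ratio of TLE over control (TMM-scaled, horizontal axis) for the members of the 16 fixed lists counted in both libraries and above the floor; each grey point is 1 miRNA, the red bar is the list's median, and the shaded band holds the middle 50% of the 220 miRNAs (-0.41 to 0.41). The miR-181 family (median 0.86) and the choroid plexus list (-0.99) lie at the ends, and most lists hold members on both sides of 0.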

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

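Most settings were fixed before the data were examined. The exceptions were the restriction to names counted in both libraries, the library totals implied by the deposited p-values and the handling of the miR-219 names. With 1 library per group nothing could be left out and variation between animals could not be measured, while depth limits the thinly counted names. No paired analysis was possible because each group holds 1 library. The 30 names at least 2-fold higher and 18 lower in TLE became 80 and 51 with no floor, 11 and 6 at a floor of 100 CPM, 48 and 45 at a 1.5-fold threshold, and 16 and 8 among names counted in both libraries. The lower names became 29 without the 10 most abundant miRNAs in the total and 35 by the library totals implied by the deposited p-values, where the higher names were 27 and 24. The split of higher against lower names also moved with scaling: by total-count scaling it was 38 against 13, and among names counted in both libraries it was 24 against 3, compared with 10 against 25 by the implied totals. DESeq2 size factors (31 and 17), 5 counts added (30 and 17), thinning (30 and 20) and miR-219 names kept apart (33 and 19) moved these counts by under 1.5 times. With no floor 416 names entered instead of 244, and the added names were thinly counted, some of them at 0 in 1 library. The number of names alone was not shown to account for the counts that moved with the floor. A single shift of all log2 ratios accounts for those that moved with scaling.

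The shift against TMM was 0.19 by total counts, 0.025 by DESeq2 size factors, -0.15 without the 10 most abundant and -0.24 by the implied totals. List medians that left their counting interval, in log2, were as follows. By total-count scaling they were 0.89 for neuron-enriched, 0.55 for activity-regulated, -0.28 for miR-34 and miR-449, 0.019 for astrocyte-associated, 0.12 for oligodendrocyte-enriched, 0.17 for vascular, -0.80 for choroid plexus, 0.28 for Dlk1-Dio3, 0.035 for let-7, 0.36 for miR-30 and 1.04 for miR-181 miRNAs. DESeq2 size factors gave -0.13 for let-7. Without the 10 most abundant they were 0.21 for activity-regulated, -1.03 for inflammation-associated, -0.32 for astrocyte-associated, -0.22 for oligodendrocyte-enriched, -1.14 for choroid plexus, -0.059 for Dlk1-Dio3, -0.31 for let-7, -0.12 for miR-17/92, 0.018 for miR-30 and 0.70 for miR-181. By the implied totals they were 0.46 for neuron-enriched, 0.12 for activity-regulated, -1.12 for inflammation-associated, -0.71 for miR-34 and miR-449, -0.41 for astrocyte-associated, -0.31 for oligodendrocyte-enriched, -0.26 for vascular, -1.23 for choroid plexus, -0.64 for other tissues, -0.15 for Dlk1-Dio3, -0.40 for let-7, -0.21 for miR-17/92, -0.069 for miR-30 and 0.61 for miR-181. At a floor of 100 CPM they were -0.029 for inflammation-associated, -0.20 for vascular, -0.74 for choroid plexus, -0.063 for Dlk1-Dio3, -0.25 for miR-17/92, 0.35 for miR-30 and 0.92 for miR-181, and with no floor 0.0045 for oligodendrocyte-enriched, 0.17 for vascular and -0.13 for miR-17/92. Summed counts gave -0.033 for neuron-enriched, 0.22 for inflammation-associated, -0.013 for oligodendrocyte-enriched, -0.24 for let-7, -0.19 for miR-17/92 and 1.07 for miR-181. Names counted in both libraries gave -0.066 for neuron-enriched, which lost both miR-9a arms. Of the single miRNAs named by rank or abundance, let-7c-5p (0.025) and let-7f-5p (0.045) turned direction, both by total-count scaling. The correlation between arms of a hairpin, 0.284, became 0.943 at the floor of 100 CPM (permutation p = 0.0173, Benjamini-Hochberg adjusted 0.0863), over 6 hairpins, and 0.9 over the 5 of these counted in both libraries (permutation p = 0.0833, adjusted 0.139). At the floor of 10 CPM it was 0.0955 among names counted in both libraries. The cause was not tested.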

Other observations

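The correlation between the arms of a hairpin was planned before the data were examined, at floors of 10 and 100 CPM; every other test in this part was chosen after the values were seen. Outside the fixed lists, the paired miRNAs miR-221-3p and miR-222-3p were both higher in TLE, with log2 ratios of 0.43 (28135 against 24168 counts) and 0.88 (8868 against 5574), both of which stayed above 0 under every scaling tried. miR-140-3p, with 35002 against 22560 counts, was at 0.84, and miR-423-5p, with 13154 against 7532, at 1.01. The 3p arms of miR-30a and miR-30e were at 1.11 and 1.15, above their 5p arms at 0.16 and 0.68. miR-341 lies between Dlk1 and Dio3 in the RefSeq table but was not among the listed members of that region.

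Known miRNAs at 0 in the control library were examined as a group. After the miR-219 names were joined, 27 known names had TLE counts and no control count, and 0 had the reverse. Of the 185 known names with 100 or more TLE counts, 13 were at 0 in control and 0 were above 0 but at least 10-fold lower there. The highest fold among the rest was 7.46. Counting against different miRNA name sets would give such a gap, but both cuts were set after the values were seen, so it does not test that explanation. Under 100 TLE counts the gap was not kept: miR-879-5p had 18 against 1 counts and was 14.3-fold higher in TLE. For miR-219a itself, a 2-fold or larger difference is argued against by the joined counts, where the largest log2 ratio of the 2 arms above the floor was 0.134 in size. Under the same rule for older names, miR-9a, miR-126a, miR-299a and miR-409a are also newer forms of names without the letter. The names miR-191a-5p, miR-378a-3p, miR-31a-5p, miR-203a-3p and miR-190a-5p, also at 0 in control, carry the letter too but are not named in that rule. Others at 0, such as miR-1839-5p and miR-1298, carry no such letter, and miR-218a-5p, which the rule does name, had counts in both libraries. For the names other than miR-219a a tissue difference cannot be told apart from missing names, because the data hold no read sequences. Against 3 control counts, such a difference would have to be at least 49.0-fold for each of the 13 names with 100 or more TLE counts. The bound was as low as 3.47-fold for miR-190a-5p among the thinly counted rest. The 27 names held 68882 TLE counts (1.35%), and the 29 numbered predictions at 0 in TLE held 78123 control counts (1.17%), so reads of the absent names may have been counted under such numbers.

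The 2 arms of a hairpin come from 1 precursor, yet often differed. Over the 40 hairpins with both arms above the floor, the log2 ratios of the arms had a Spearman rho of 0.284 (permutation p = 0.0759, Benjamini-Hochberg adjusted over 5 relations 0.139), and over the 37 with counts in both libraries 0.0955 (permutation p = 0.575, adjusted 0.575); these are correlations across hairpins, which are not independent replicates. The amount of precursor moves both arms alike, so on its own it gives no difference between arms, and it was not tested separately. In 22 of the 37 hairpins the arms had counting intervals that did not overlap. Among them were miR-345 (-0.35 for 5p and 2.77 for 3p), miR-342 (-0.55 and 1.5), miR-132 (-0.49 and 1.19) and miR-92b (1.56 and -0.30). Counting error is argued against by the median difference between arms, 0.502, where counting error alone gave 0.11 with an upper limit of 0.16. Neighbouring hairpins within 10 kb (135 pairs) differed by a median of 0.50 against 0.57 for shuffled pairs (one-sided permutation p = 0.213, adjusted 0.266). Most of these pairs join hairpins of the Dlk1-Dio3 region, which recur in many pairs, so the comparison mainly describes that region. For the differences between arms, arm-specific processing, library preparation and counting against different name sets remain open. Differences between the rats behind each library remain open too. With 1 library per group, how far preparation alone moves an arm was not measured.

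A lower share of choroid plexus in the TLE tissue is a candidate explanation for the low miR-448-3p, miR-204-5p and miR-204-3p. The scaling between the libraries is argued against, since miR-204-3p, the smallest of the 3 differences, was still at -0.556 under the scaling that raised it most. The choroid plexus list gives no separate evidence, since its only 2 members above the floor are those 2 arms of miR-204. The miR-34 and miR-449 list of ciliated cells, which choroid plexus also holds, had a median of -0.47 at percentile 24.1 of random lists (9.61 among names counted in both libraries) and again only 2 members, so the explanation cannot be told apart from a difference within the hippocampus. Among other miRNAs within Htr2c, miR-1912-3p also was lower (5 against 41 counts) and miR-764-3p was higher (24 against 10), both under the floor of 10 CPM. miR-1298 was at 0 in control, where a difference cannot be told apart from a missing name. Htr2c is also expressed in hippocampal neurons, and mRNA of choroid plexus was not analysed here.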
